A study of Arabidopsis thaliana with 6 samples.

How the data were processed

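The study measured total RNA of Col-0 seedlings in 6 samples, 3 sprayed with mock solution and 3 with 10 µM NJ15, each on 1 Affymetrix array. Per the labels' protocols, RNA was extracted with a plant RNA kit and biotin-labelled with an Affymetrix kit for 3 prime in vitro transcription. Per the submitters' processing notes, R 2.7.2 was used. The background correction, normalization and summarization that made the values are not given in the sources used here.

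The deposited values are 1 log2 expression value per probe set and array, as read from their range of 5.30 to 14.04; the log base rests on that range and not on a statement by the authors. The deposited columns have nearly equal quantiles. Most probe sets hold 6 nearly equal values, as given next, so this cannot show whether the arrays were scaled to each other before deposit. In 16602 of the 22746 tested probe sets (73.0%) the 6 values spanned no more than 0.01 log2 units, and in 16518 of them less than 0.001. These flat probe sets had a median level of 6.88 and the varying ones 8.15; which step of the processing made them flat was not tested. No statement about a change can be made for a transcript measured by a flat probe set, and a fold change of a varying one may be affected too. No scanner values were used here, so signal over background is unknown.

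Values were used as deposited, with no further normalization, no pseudocount and no filter on dim probe sets; the 64 control probe sets were left out of the tests. To keep rounding noise out, each probe set was shifted by its value on 1 array and rounded to the decimals of the table before fitting, which leaves differences between arrays unchanged. NJ15 was compared with mock by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, where at least 5 members were measured, adjusted over the 8 lists that qualified. Single summary values were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 arrays against 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

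Gene names came from the platform annotation, updated through a gene table of assembly TAIR10.1 that was used for names only. Of the tested probe sets, 13513 were paired with 1 gene, 503 with several and 8730 were not listed, so they are unnamed here, not without a gene. Of the single-gene probe sets, 13436 matched a locus, and 13355 genes had at least 1. Where a gene had several probe sets, the one with the highest mean over all 6 arrays was used. The 28 gene and marker lists, with 528 distinct loci, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Only 81 of the 528 loci had a named probe set, so most lists were tested on a few members or not at all.

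Named genes were, among single-gene probe sets with the highest mean per gene, the 10 largest rises and the 10 largest falls past the threshold whose 3 NJ15 arrays all lay on one side of the 3 mock arrays, with ties taken in order of probe set. For each list, up to 3 members with the smallest p were named as well, past the test or not. If fewer than 10 genes passed in a direction all were to be named, and if none passed, the 10 with the smallest p, said not to pass. Genes called only in an alternative were not to be named by the rule; Fes1A, AT5G51440, AT2G20560, AT1G67360, AT2G29500, CML38, LHCB4.2, IAA20, IAA29 and the unnamed probe sets were singled out after their values were seen, as were the genes in the closing section.

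Before use, the fit was tested on simulated data drawn from each probe set's own mean and spread, with 50 varying probe sets changed in the NJ15 arrays for each amount. Over all 22746 probe sets, 44%, 72%, 82% and 86% of those changed by 1, 2, 3 and 4 log2 units were called, with 48 false calls. Over the 6144 varying probe sets the shares were 62%, 80%, 94% and 94%, with 8 false calls. The simulated noise was independent between probe sets and between arrays. In the real arrays, deviations from the group means were shared, with r = 0.586 between mock replicate 1 and NJ15 replicate 1. The shares and false calls therefore hold for independent noise and do not give what the fit can find in the real data.

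The alternatives were quantile normalization, centring of each array on the common median, a filter that removed probe sets with low means, a prior with an intensity trend and robust estimation, the replicate number as a block, each array left out in turn, stricter thresholds, 1 probe set per gene, camera with an estimated correlation, and fry. The camera test has no robust option, so the gene lists were run with the intensity trend only. A pseudocount did not apply, because the values were already on a log scale. Fits on varying probe sets only and with the mean of the photosynthetic markers as a covariate were added after the data were examined.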

Results

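Transcript levels were measured in Arabidopsis thaliana seedlings of the Col-0 wild type after treatment with NJ15, an ethyl ester of a tetrazole acetic acid that carries a dichlorophenyl ring. Seedlings stood upright on plates for 4 days, received a spray of either mock solution or 10 µM NJ15, and were then rotated by 90 degrees to start a gravitropic response. RNA was taken 8 h later and hybridised to Affymetrix arrays. The 6 arrays form 2 groups, 3 mock and 3 NJ15, which the labels call biological replicates, and the number of arrays limits the precision of every value. The deposited table holds 22810 probe sets on a log2 scale, and 22746 of them were tested after 64 control probe sets were left out. Array medians lay close together, at 7.24, 7.26 and 7.25 in the mock arrays and 7.27, 7.27 and 7.26 in the NJ15 arrays. Of the tested probe sets, 16602 (73.0%) had 6 values that spanned no more than 0.01. These are called flat here, and the remaining 6144 are called varying. Flat probe sets hold the array medians together, so the close medians do not show how alike the arrays were.

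The first comparison asked which transcripts differed between NJ15 and mock seedlings 8 h after rotation. Hop3, which encodes a co-chaperone that links the heat shock proteins HSP70 and HSP90, was higher in all 3 NJ15 arrays. Its level was 6.65 ± 0.11 (SD, n = 3) in mock and 8.68 ± 0.10 (SD, n = 3) in NJ15 seedlings, a log2 fold change of 2.03 with a standard error of 0.08 (limma, adjusted p = 0.0456). Among probe sets without a gene name, 2 rose, by log2 fold changes of 3.43 and 4.28, both with a limma adjusted p of 0.0456. These 2 probe sets fell outside the rule for named genes and were chosen after their values were seen. 2A6, which encodes a member of the family of oxygenases that use iron and oxoglutarate, was lower in all 3 NJ15 arrays, with a log2 fold change of -0.20, a standard error of 0.0089 and a limma adjusted p of 0.0456. The adjusted p of 0.0456 was the same for all 4 and for flat probe sets whose unadjusted limma p, 8.81e-05, was higher than that of any of the 4. It therefore depended on the calls on flat probe sets. Hop3 kept its size without any 1 array, between 1.97 and 2.08, but its adjusted p then lay between 0.109 and 0.172. The log2 fold change of 2A6 likewise stayed between -0.20 and -0.19 in the leave-outs, with adjusted p between 0.115 and 0.174.

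In all, limma called 44 of the 22746 probe sets, 19 higher and 25 lower in NJ15, and 1253 had an unadjusted p under 0.05. Of the calls, 40 fell on flat probe sets, on which no change exceeded 1e-08 on the log2 scale. The rule for named genes took 20 genes, and 18 of these were flat, among them AT5G60720 with a change of 8.67e-09 and AT2G29020 with a change of -1e-08. Changes of this size describe the numerical form of the table and not a measurable difference in transcript level. The count fell to 11, 4 and 15 without mock replicates 1, 2 and 3 and to 7, 4 and 7 without NJ15 replicates 1, 2 and 3. With limma it was 0 after quantile normalization, where 3347 had an unadjusted p under 0.05, and it reached 17165, with 236 higher and 16929 lower, when each array was centred on a common median, 16591 of them flat.

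A fit over the 6144 varying probe sets alone, chosen after the data were examined, called 4 probe sets, all higher in NJ15, and 3 of these were also called over all probe sets. Hop3 had an adjusted p of 0.0053 in this fit, and the 2 unnamed probe sets had 0.0053 and 0.0173 (limma). The added call was Fes1A, which encodes an exchange factor of cytosolic HSP70. Fes1A and the other genes named in this paragraph beyond Hop3 and 2A6 were chosen after their values were seen. Fes1A stood at 7.08 ± 0.20 (SD, n = 3) in mock and 9.002 ± 0.17 (SD, n = 3) in NJ15 seedlings, a log2 fold change of 1.92 with a standard error of 0.14 (limma, adjusted p = 0.0463). With the mean of the photosynthetic markers as a covariate the fit called 4 probe sets as well, 3 of them shared, and Fes1A was lost (limma, adjusted p = 0.0721). The call gained with the covariate was a further unnamed probe set (limma, adjusted p = 0.0470, against 0.0965 without it). 2A6 was called neither without the covariate (limma, adjusted p = 0.289) nor with it (adjusted p = 0.218). At an adjusted p under 0.1 the fit held 25 probe sets, 23 higher and 2 lower, and 10 of them carried 1 gene name. The named ones included AT5G51440, a mitochondrial small heat shock protein, at a log2 fold change of 3.61 (limma, adjusted p = 0.0965), AT2G20560, a DnaJ protein, at 2.46 (adjusted p = 0.0550), and AT1G67360, a lipid droplet protein, at 2.02 (adjusted p = 0.0965). The groups did not overlap in 12.5% of the varying probe sets, where chance gives 10% and the highest of the 9 other splits of the arrays gave 23.5%. Among those also at least 2-fold apart, 112 were higher and 6 lower in NJ15. Their total was 118, and the highest of the 9 other splits gave a total of 98. Leaving out single arrays gave 0, 0 and 3 limma calls without mock replicates 1, 2 and 3, at 594, 386 and 693 with an unadjusted p under 0.05, and 1, 0 and 0 calls without NJ15 replicates 1, 2 and 3, at 331, 320 and 485.

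**Figure D1:**
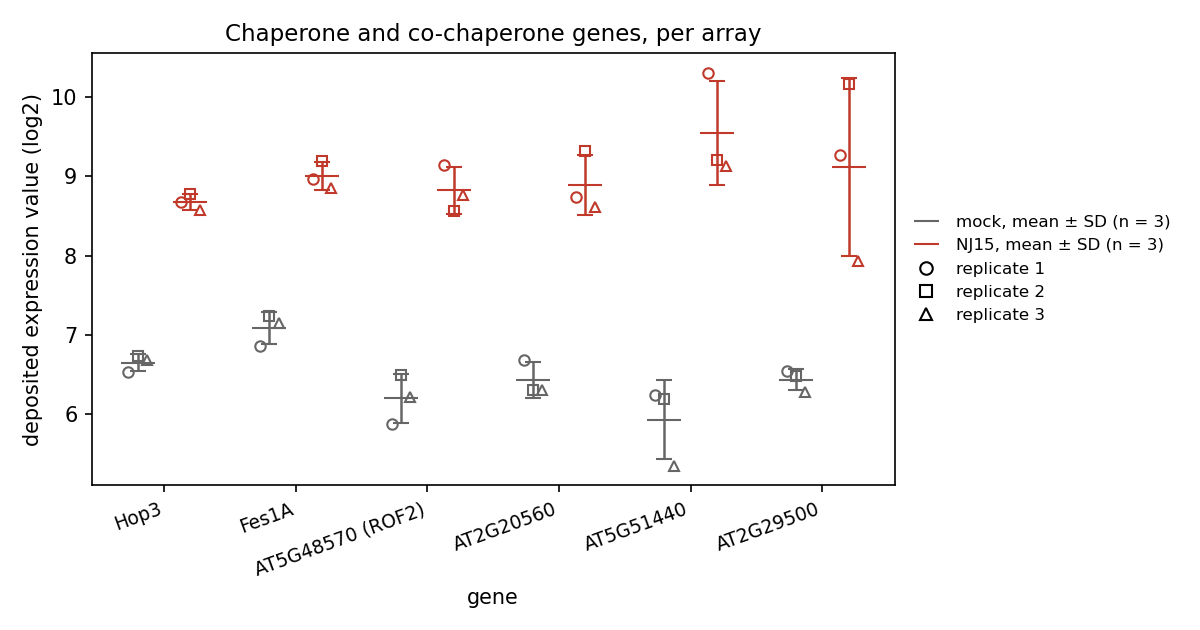
Deposited log2 expression values (vertical axis) of 6 chaperone and co-chaperone genes (horizontal axis) in each mock (grey) and NJ15 (red) array, with the group mean and SD as bars (n = 3). The NJ15 arrays lie above all mock arrays for each gene, from 6.65 to 8.68 in the group means of Hop3, and the AT2G29500 values spread widely in NJ15 with an SD of 1.12.

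Heat shock genes were a list fixed before the data were examined, but only 2 of its 15 members had a named probe set, too few for a list test. ROF2 (AT5G48570), a heat-inducible immunophilin, had a log2 level of 6.20 ± 0.31 (SD, n = 3) in mock and 8.82 ± 0.30 (SD, n = 3) in NJ15 seedlings. Its log2 fold change of 2.62 passed the test adjusted over the list alone (limma, adjusted p = 0.0007) but not over all probe sets (adjusted p = 0.154). ATHSP22.0, a small heat shock protein of the endoplasmic reticulum, had a log2 fold change of 0.49 and passed neither test (limma, adjusted p = 0.0838 over the list alone). Without NJ15 replicate 2 it was 0.32.

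Auxin redistribution drives gravitropic bending, so the auxin-induced genes were the first gene group compared. Of 30 listed genes, 10 had a named probe set and 7 of these varied. None passed the test over all probe sets or adjusted over the list alone. The camera test of the list against all other genes gave an adjusted p of 0.899 (limma) in the lower direction, while the mean log2 fold change of the 7 varying members was 0.03 and their median 0.08, both of opposite sign to the test. Their mean level was 8.08 ± 0.17 (SD, n = 3) in mock and 8.11 ± 0.15 (SD, n = 3) in NJ15 seedlings (two-sided exact permutation test, p = 0.8, with 0.1 the smallest p that 3 against 3 allows). GH3.3, which encodes an enzyme that conjugates auxin to amino acids, had a log2 fold change of 0.35, and LBD16, a transcription factor of lateral root initiation, had one of -0.45; neither passed (limma, adjusted p = 0.849 and 0.937). LBD16 had -0.71 without mock replicate 3. After quantile normalization and after centring the camera direction turned to higher, with adjusted p = 0.0151 and 0.00148 (limma), although the mean log2 fold change of all 10 measured members, 0.02 in the deposited values, was 0.0053 and 0.00051 there.

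**Figure D2:**
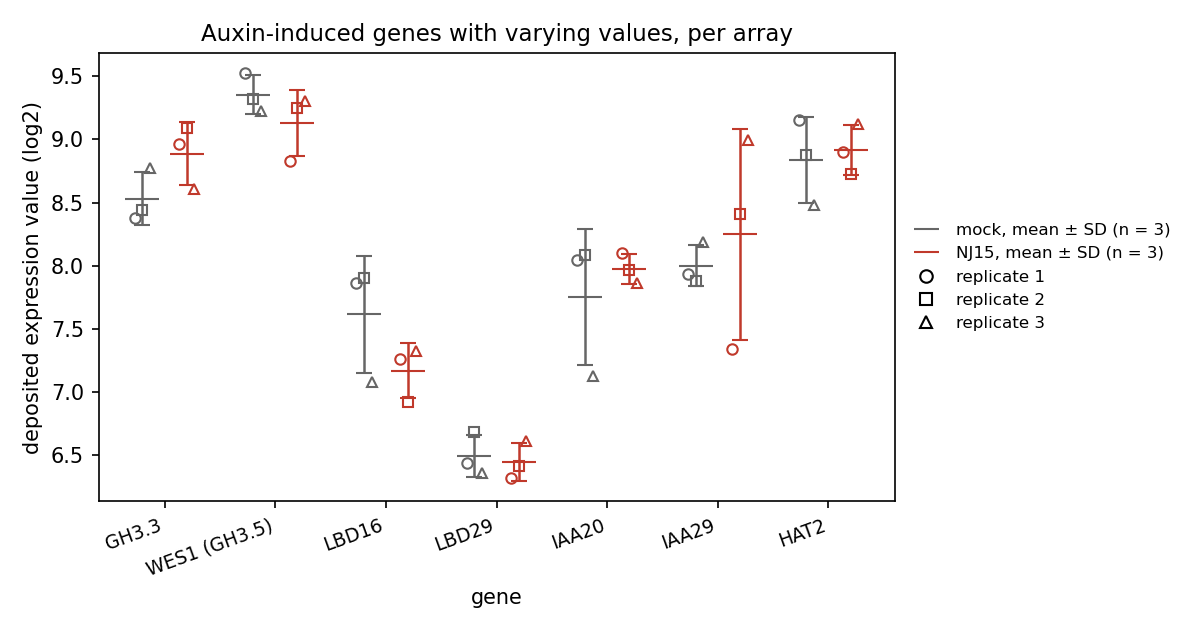
Deposited log2 expression values (vertical axis) of the 7 auxin-induced genes whose values varied (horizontal axis), in each mock (grey) and NJ15 (red) array, with the group mean and SD as bars (n = 3). Mock and NJ15 arrays overlap for every gene shown, including GH3.3 with a log2 fold change of 0.35.

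Among the other auxin lists, 7 of 27 Aux/IAA repressors had a named probe set and 2 varied, IAA20 and IAA29, with log2 fold changes of 0.22 and 0.25, both chosen after their values were seen. IAA20 turned to -0.09 without mock replicate 3 and had 0.37 and 0.39 without mock replicates 1 and 2. IAA29 turned to -0.12 without NJ15 replicate 3 and had 0.70 without NJ15 replicate 1. None passed, nor did the list (camera, adjusted p = 0.867). Of the auxin synthesis and conjugation genes, 5 of 28 were measured, and the only varying one was AT1G14130 (DAO1), an auxin oxidase. Its log2 fold change was 0.40 with the groups apart, which did not pass (limma, adjusted p = 0.0688 over the list alone). The list passed only without probe sets of low mean (camera, adjusted p = 0.434 in the deposited values, 0.497 with an estimated correlation and 0.0378 without low means). That filter removed YUC4 and UGT84B1, at levels of 6.26 and 6.28, so fewer than 5 members were left. Auxin transport had 2 measured members, of which WAG2 varied and had a log2 fold change of -0.33 without passing; it was -0.12 without mock replicate 1, -0.62 without mock replicate 3 and -0.17 without NJ15 replicate 2. No SAUR gene and no auxin receptor or ARF had a named probe set, and the 1 measured gravity sensing gene, AT1G72490, was flat.

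The detoxification list other than glutathione transferases was higher in NJ15 seedlings against all other genes (camera, adjusted p = 1.06e-05), but not with an estimated correlation (adjusted p = 0.261 with an estimated correlation). Of 24 listed genes, 6 were measured and 5 varied. UGT73B4 and UGT73B5, which encode glycosyltransferases of stress and defence compounds, and AER, which encodes an alkenal reductase, passed when adjusted over the list alone. Their log2 fold changes were 0.47, 0.45 and 1.71 and their adjusted p-values 0.0093, 0.0413 and 0.0413 (limma), with all 3 NJ15 arrays above all mock arrays. None of the list's members passed over all probe sets. The 5 measured glutathione transferases of 23 all varied, and the list did not pass in the deposited values (camera, adjusted p = 0.296; adjusted p = 0.396 with an estimated correlation), with log2 fold changes of 1.57 for GSTU25, 0.43 for GSTU16 and -1.05 for GSTU20. None of these passed, and GSTU20 had -0.38 without mock replicate 3 and GSTU25 0.98 without NJ15 replicate 1. The list test passed after quantile normalization and after centring (camera, adjusted p = 0.00021 and 1.19e-06). These scalings shifted the median log2 fold change of all probe sets by -0.013 and -0.018. GSTU25, GSTU16 and GSTU20 were lower there too, which cannot decide whether the list rose against other genes. The passes came with this shift and are not read as a rise of the list.

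The touch and cold list was also higher in NJ15 seedlings (camera, adjusted p = 0.00015), and this call too was lost with an estimated correlation (adjusted p = 0.261). Of its 13 genes, 5 were measured, 4 varied and none passed in either adjustment. CML23, a calmodulin-like protein, had a log2 fold change of 1.21 with the groups apart. STZ, a zinc finger repressor also known as ZAT10, had one of 2.82, and the groups overlapped because mock replicate 1 stood at 9.93 while mock replicates 2 and 3 stood at 6.94 and 6.90. Mock replicate 1 was likewise the highest mock array for CML23, at 7.52 against 6.53 and 6.44. The oxidative stress list, with 2 of 16 genes measured, shares STZ and adds AT2G21640 at a log2 fold change of 1.73, which did not pass and was 1.12 without NJ15 replicate 1 and 2.61 without NJ15 replicate 3.

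**Figure D3:**
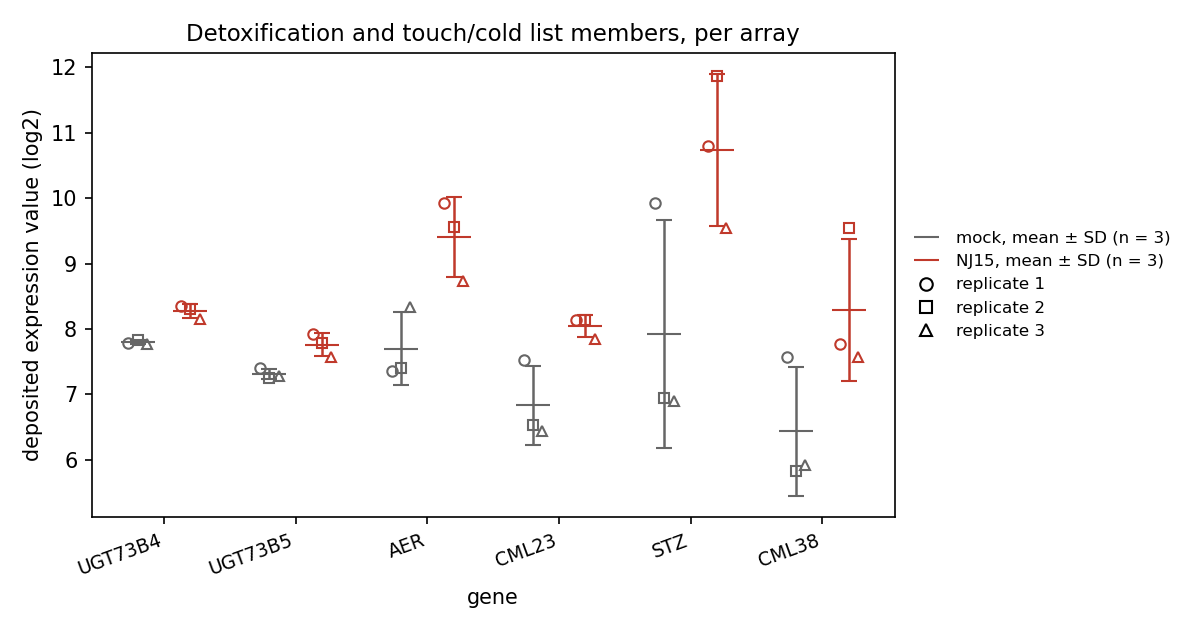
Deposited log2 expression values (vertical axis) of 3 detoxification genes (UGT73B4, UGT73B5, AER) and 3 touch and cold genes (CML23, STZ, CML38) in each mock (grey) and NJ15 (red) array, with the group mean and SD as bars (n = 3). Mock replicate 1 stands at 9.93 for STZ, inside the NJ15 range, while the groups are apart for the detoxification genes.

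Among cell wall genes, 8 of 21 xyloglucan endotransglucosylases were measured and the 6 that varied had a mean log2 fold change of -0.54. The list did not pass (camera, adjusted p = 0.123), and its camera direction turned to higher when arrays were centred on the common median, although XTH20, XTH16 and XTH18 then had log2 fold changes of -0.52, -0.84 and -0.72. Centring moved all probe sets of an array alike, flat ones included, so this turn is not read as a rise of the list. The list passed in the lower direction over varying probe sets alone (camera, adjusted p = 0.0123; adjusted p = 0.233 with an estimated correlation), without probe sets of low mean (0.0378) and without NJ15 replicate 3 (0.0294). XTH20, XTH16 and XTH18 had log2 fold changes of -0.50, -0.82 and -0.70 and none passed. XTH16 had -0.32 without mock replicate 3 and XTH18 had -0.37 without mock replicate 2. Of 16 expansins, 9 were measured and 4 varied. The list did not pass in the deposited values (camera, adjusted p = 0.123; adjusted p = 0.331 with an estimated correlation), and it passed in the higher direction without probe sets of low mean (0.0378). It also passed after quantile normalization (0.0284) and after centring (0.0102). EXPB1 and EXPA8 had lower log2 fold changes there, but these scalings also shifted the median of all probe sets, by -0.013 and -0.018. Their values therefore cannot decide on the list, and the passes are not read as a rise of it. EXPB1 and EXPA8 had log2 fold changes of 0.53 and 0.21 with the groups apart, and neither passed. EXPA8 had 0.13 without mock replicate 1.

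In 15 lists only 1 to 4 members were measured, and 5 lists had none. Where a member of the thin lists varied, none passed apart from ROF2: GRX480, a glutaredoxin of salicylate signalling, had a log2 fold change of 1.14, COR47 and LTI30, both dehydrins of drought and cold, had 0.24 and 0.13, RR16 (ARR16), a cytokinin response regulator, had -0.20, the gibberellin receptor GID1B had 0.06, the mitotic kinase AUR1 had -0.08, and the clock gene GI had 0.23. Without mock replicate 3, RR16 turned to 0.21, GI to -0.26, GID1B to -0.04 and LTI30 to -0.07, and RR16 turned to 0.10 without NJ15 replicate 1. Without mock replicate 1, RR16 had -0.56, GI 0.58, LTI30 0.34 and GID1B 0.10. Without mock replicate 2, GI had 0.36 and GID1B 0.12. LTI30 had 0.02, 0.05 and 0.33 without NJ15 replicates 1, 2 and 3. Without NJ15 replicates 2 and 3, RR16 had -0.30 and -0.38 and GID1B 0.01 and 0.10. GRX480 had 0.73 without NJ15 replicate 2, COR47 had 0.12 without NJ15 replicate 1, and AUR1 had -0.04 without mock replicate 3. The jasmonate and flavonoid lists, with 3 and 2 measured members, the 2 ethylene genes and the 2 root hair genes were flat. RTE1 of the ethylene list passed when adjusted over the list alone (limma, adjusted p = 0.0374) with a change of -4.82e-07. In total the list rule named 53 genes, of which 23 were flat: IAA18, IAA33, IAA30, PID2, YUC4, YUC6, AT1G72490, RTE1, EIN3, ARR15, GID1A, COR15A, PDF1.2, JMT, THI2.1, WRKY53, AT1G76640, EXPA15, AUR2, DFR, UF3GT, EXPA7 and EXPA18. No list member passed over all probe sets.

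Markers of green tissue did not separate the groups. The 4 measured photosynthetic genes of 32, LHCB4.1, LHCB4.2, RCA and PRK, had a mean log2 level of 11.42 ± 0.66 (SD, n = 3) in mock and 11.40 ± 0.35 (SD, n = 3) in NJ15 seedlings (two-sided exact permutation test, p = 1). LHCB4.1, RCA and PRK had log2 fold changes of 0.12, -0.19 and -0.03, and none passed. Their directions rested on single arrays: LHCB4.1 had -0.12 without mock replicate 1, and RCA and PRK had 0.20 and 0.15 without mock replicate 3 and 0.06 and 0.16 without NJ15 replicate 1. Within the mock group this mean ran from 10.75 in replicate 1 to 12.06 in replicate 3. Markers of the endodermis, of vascular tissue and of the root tip had no named probe set, so the share of those tissues was not analysed here.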

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

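The control probe sets of the array took no part in the comparisons above, and 29 of the 64 varied. In 4 of these 29 all 3 NJ15 arrays lay above all 3 mock arrays, where chance gives 5% of probe sets, and in 1 all lay below. Most of these 4 measure GAPDH, so they are not independent and their number cannot be weighed against the 5%. One GAPDH control for the 3 prime end of this glycolytic enzyme's transcript stood at 11.80 ± 0.10 (SD, n = 3) in mock and 12.41 ± 0.20 (SD, n = 3) in NJ15 arrays, a difference of 0.61 on the log2 scale. One for the 5 prime end differed by 0.49 and the middle GAPDH control by 0.25. The other 3 prime and 5 prime GAPDH controls differed by 0.11 and 0.39, with the groups overlapping. A ubiquitin control differed by 0.036, with an SD of 0.01 in each group. The 25S ribosomal RNA control was the one below, at 11.49 ± 0.02 (SD, n = 3) in mock and 11.05 ± 0.18 (SD, n = 3) in NJ15 arrays.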

How the results depend on the processing

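The fits on varying probe sets only and with a covariate were chosen after the data were seen. The 44 calls over all probe sets (19 higher, 25 lower, 4 on varying probe sets) became 0 after quantile normalization, without probe sets of low mean, with the trend and robust prior and with the replicate block, at 3347, 898, 886 and 1208 probe sets with an unadjusted limma p under 0.05; the cause was not tested. Centring on the median gave 17165 calls (236 higher, 16929 lower, 574 on varying probe sets), since it moves each flat probe set by the array's shift. A threshold of 0.01 left 1 call, 0 higher and 1 lower and 0 on varying probe sets, and a 2-fold limit left 3, all higher and varying, with 0 lower. The fit on varying probe sets gave 4 calls, all higher, with 0 lower. With 1 probe set per gene, which tests named genes only, 2 of the calls varied. Single leave-outs gave 4 to 15 calls, 0 to 4 higher, 2 to 11 lower and 0 to 1 on varying probe sets.

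Over the varying probe sets alone, the 4 calls became 9 after quantile normalization, 8 with a span above 0.1, 25 at an adjusted p under 0.1, 2 at 0.01, 0 with the replicate block (449 at an unadjusted limma p under 0.05) and 0 to 3 in the leave-outs; the cause was not tested. The 2 gene lists past the test became 5 after quantile normalization, 5 after centring, 5 without probe sets of low mean, and the cause was not tested. The lists gained were auxin-induced genes, glutathione transferases and expansins in the first 2, and expansins, xyloglucan endotransglucosylases and auxin synthesis in the last. They became 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation on varying probe sets, and 2 to 3 in the leave-outs. The mean log2 fold change of the auxin-induced genes, 0.02, ran from -0.049 to 0.072 in the leave-outs. It was 0.0053 after quantile normalization and 0.00051 after centring, where the list test passed in the higher direction. Centring gave 16591 flat probe sets a lower or higher call by construction, while 7 of the 10 list members varied; for quantile normalization the cause was not tested. Averaging probe sets changed nothing, since no member had a second one.

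The deviations of same-numbered arrays from their group means correlated at r = 0.586 for number 1, the highest of all pairs, at 0.192 for number 3 and at -0.305 for number 2 over varying probe sets. By the same deviations mock replicate 2 correlated best with NJ15 replicate 3, and mock replicate 3 with NJ15 replicate 2. In the values themselves mock replicate 3 correlated more with NJ15 replicate 3 (r = 0.923) than with NJ15 replicate 2 (r = 0.896). The main fit used no pairing, as set before the data were examined, since the labels name no batch. None of the 4 called varying probe sets changed sign in the alternatives run over all probe sets, while 16 of the 40 called flat ones did after quantile normalization and 16 after centring. Pseudocount alternatives were not run because the values are on a log2 scale, and gene lists were run with the intensity trend only because camera has no robust prior. The number of arrays and the unknown signal over background limit what can be seen.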

Other observations

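The tests on small heat shock proteins, flat probe sets, the mock arrays, the counts of probe sets and the direction of large differences were chosen after those results were seen; the splits of the arrays for the gene lists were set before. Among all genes with a single-gene probe set, 48 were at least 2-fold apart with no overlap of the groups, 47 higher and 1 lower in NJ15. They include the list members ROF2, AER, GSTU25 and CML23. Apart from the chaperones already given they included AT3G09440, a cytosolic HSP70, at a log2 fold change of 1.26, the nuclear exportin XPO1B at 1.15, the ubiquitin ligase PUB19 at 1.70, and AT5G16980, a relative of AER, at 1.24. The lower gene was AT1G62500, at -1.05, where mock replicate 3 stood at 9.16 and mock replicates 1 and 2 at 7.73 and 7.78. None of these 5 passed in the fit on varying probe sets (limma, adjusted p from 0.238 to 0.678). Larger rises included AT5G17350, AT4G27657 and AT1G15010, at 2.25, 2.18 and 2.07, which did not pass either. In these, mock replicate 1 was the highest mock array, as for AT4G27657 at 8.29 against 6.59 and 6.22. Not every large rise had this pattern: AT3G14200, at 2.12, stood at 7.34 in mock replicate 1, against 7.72 and 7.04.

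Small heat shock proteins bind unfolding proteins under heat. Of the family's 10 genes with a named probe set 8 varied, and 5 of these 8 were higher in every NJ15 array than in any mock array: AT5G51440, AT1G54050, AT2G29500, AT2G19310 and AT5G37670, at log2 fold changes of 3.61, 3.03, 2.68, 1.70 and 1.502. ATHSP22.0 and AT1G53540 had 0.49 and 0.17, and AT4G21870 had -0.48. Single arrays weighed on some of these values. NJ15 replicate 2 stood at 11.24 for AT1G54050, against 8.36 and 7.69 in NJ15 replicates 1 and 3. For AT1G53540 it stood at 7.06, against 6.56 and 6.43. Mock replicate 1 stood at 7.93 for AT4G21870, against 9.16 and 9.13 in mock replicates 2 and 3. None passed the threshold of 0.05 alone.

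The median log2 fold change of the 8 varying family members was 1.60, and at its lowest 1.47 with NJ15 replicate 2 left out, so no single array set it. The photosynthetic marker means of the NJ15 arrays, 11.004 to 11.617, lay inside the mock range of 10.750 to 12.062, while the lowest NJ15 mean of the family exceeded the highest mock mean by 0.951 (SD 0.12 in mock and 0.53 in NJ15, n = 3), which argues against the share of green tissue, as far as these markers measure it, as the whole cause. A response of the family to NJ15 stays open: against the other varying genes camera gave p = 3.59e-08, and p = 0.0239 with an estimated correlation, but the family was picked after some of its members had been seen. Of the 10 splits 1, the real one, gave a p as small, the smallest p for the family in the other 9 was 0.00056, and 10 splits are too few for a share under 0.05. Both groups were sprayed and turned per the labels, and no other cause of chaperone induction was tested.

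Mock replicates 1 and 3 were the arrays farthest apart, with 839 varying probe sets at least 2-fold different and a correlation across varying probe sets of 0.857. The 9 varying nuclear genes whose symbol or synonyms name a photosystem, its antenna or Rubisco were all higher in mock replicate 3, by a median of 1.79, with PSAN at 3.095 and LPA19 at 0.14. The 19 plastid ones differed by a median of only 0.109, from -0.44 for psaC to 1.41 for rbcL. A different share of green tissue therefore stays open beside light or time of harvest, which were not tested. Of the other varying probe sets, 506 were at least 2-fold higher and 325 at least 2-fold lower in mock replicate 3. Named genes ran from -3.69 for AT4G27652 to 5.47 for AT5G48490, with STZ of the touch and cold list at -3.03. The cause of these differences was not tested. The actin and ubiquitin controls differed by a median of -0.0192, which argues against a difference in scaling of the deposited values. Whether the arrays were scaled to each other before deposit is not known, so an earlier difference in scaling cannot be judged.

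The calls on flat probe sets rested on changes of no more than 1e-08 on the log2 scale, so they are numerical residue and not differences in transcript level. Which step of the processing left this residue was not tested. With mock replicates 1 and 2 and NJ15 replicate 1 set against the rest, 61 flat probe sets were called, against 40 in the real comparison, and the total was 65 against 44; 2 of the 10 splits gave as many calls.

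On varying probe sets the real split gave 4 calls and the highest other 0 (1 of 10 splits). For gene lists the real split gave 2 and the highest other 3 (4 of 10 splits), and for the auxin-induced genes the real p was 0.899 and the smallest other 0.0108 (10 of 10 splits). For the excess of one direction among varying probe sets at least 2-fold apart, the real split gave 106 and the highest other 50 (1 of 10 splits). The total of such probe sets in both directions was 118 in the real split and 98 in the highest other. With 10 splits no share can fall under 0.05.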
